A study of Mus musculus with 18 samples.

How the data were processed

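Bulk RNA of back skin was measured in 18 FVB mice aged 6 months, each sequenced as its own library: 6 WT mice, 6 mice labelled N-IKKa and 6 mice labelled C-IKKa. Per the labels, RNA was extracted with TRIzol and RNeasy MinElute columns, libraries were made with a stranded mRNA kit, and paired-end reads were taken on a NovaSeq instrument. Per the submitters' processing notes, reads were counted with featureCounts on the genome build GRCm39. The versions, the strand setting, the aligner, the annotation release and the tool used for scaling were not given in the sources used here.

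The deposited table gave 1 signal per gene and library, a normalized count, for 55357 genes and 18 libraries. In each library, 100% of the non-zero values were whole multiples of 1 step within 0.001 reads. The values were therefore read as gene counts that the authors had divided by 1 size factor per library, and the counts were recovered by dividing by the step. Recovered reads ran from 11.1 to 15.7 M (megareads) per library, and 1 read was worth 0.816 to 1.20 normalized counts. A listed value of 0 allows up to 3 counts, which is 2.45 to 3.61 normalized counts depending on the library. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries were copies of each other: the smallest chi-square per gene between any pair was 6.17.

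Values were analysed as log2(normalized count + 1). Genes with a normalized count of at least 10 in at least 6 libraries were tested, which left 17667 genes. All 18 libraries entered 1 linear model with a mean per group, with 15 residual degrees of freedom, and the 3 pairwise contrasts were tested with limma 3.58.1 (empirical Bayes with a mean-variance trend) in R 4.3.3. P values were two-sided and were adjusted by the Benjamini-Hochberg method within each contrast. A gene was called at an adjusted p below 0.05. Fold changes are differences of mean log2 values, with the moderated standard error (SE). Chuk and the genes fixed in advance that fell below the filter were compared by exact two-sided permutation tests of mean log2 values, 6 libraries against 6. These formed a family of 15 tests, in which the smallest possible p was 0.00216. The use of the permutation test for the 4 genes below the filter was chosen after their values were seen.

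The groups, the comparisons, the filter, the tests, 37 gene lists and 27 single genes were fixed before the data were examined. The lists covered keratinocyte layers, hair follicle and gland, immune and other skin cell types, and signalling and stress pathways. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 111 tests, and again with a correlation estimated from the data. Genes were named by a rule with 3 parts. First came up to 10 genes per direction with the largest fold change among called genes that were at least 2-fold apart, had a mean of at least 50 in the higher group and had no overlap between libraries, leaving out numbered gene models. Then came the genes fixed in advance. Of each list described, up to 4 called members were named, or else the 2 with the smallest p. Any other gene named was chosen after its values were seen.

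Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM, median-of-ratios and quantile scaling, edgeR 4.0.16 (robust quasi-likelihood) and DESeq2 1.42.0 on recovered reads, robust moderation, array weights, the pair of compared groups alone, each library left out in turn, a sex covariate and a 2-fold limit. After the data were seen, further alternatives were added. These were a covariate for the mean of the hair shaft list, that covariate with sex, the same fit without the 6 libraries in which that mean exceeded 8, and reads thinned to the smallest library. The covariate and the cut at 8 both use the hair shaft list, so these fits do not test that list itself. A library was read as male where Ddx3y exceeded 500 normalized counts.

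The model was tested on simulated data made from these libraries. With 17442 genes tested, 30% of genes simulated with a 1.5-fold change were called in C-IKKa against WT, 68% with a 2-fold change, 100% with a 4-fold change and 96% with an 8-fold change. Of the calls, 3.61% were false, and 0 genes were called in a simulated comparison of N-IKKa with WT without any change. Simulated genes varied independently of each other, and only abundant genes were changed. The rates therefore do not cover variation shared by many genes, such as that of hair follicle genes here, and the recovery does not cover genes with low counts.

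Gene neighbours and exon overlap came from an annotation of the earlier mouse build, matched by gene identifier for 52081 of 55357 genes, so no coordinates are given. Of 47 protein-coding genes with at least 95% of their exon length overlapped by exons on the opposite strand, 93.6% were listed at 0 in every library, against 20.6% of 16603 genes without such overlap. Among genes picked by the naming rule, the overlapped shares included 74.0% for Tnnc2, 67.9% for Tagln, 24.8% for Krt6a and 23.4% for Ccnd1. They also included 18.0% for Dbp, 14.4% for Pglyrp2 and 11.7% for Icam1. The strand setting was not given, so values of overlapped genes are uncertain. Listed genes Krt85 and Nrg1 were not found under these symbols and were not used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.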

Results

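Back skin of FVB mice aged 6 months was profiled by bulk RNA sequencing in 3 groups of 6 mice. WT mice were compared with N-IKKa mice, which carry exogenous IKKα in the nuclei of keratinocytes, and with C-IKKa mice, which carry it in the cytoplasm. IKKα, encoded by Chuk, is a kinase of the NF-kB pathway that also acts in keratinocyte differentiation. Libraries held 11.1 to 12.6 M counted reads in WT (mean 11.8), 12.0 to 14.6 M in N-IKKa (mean 13.4) and 12.6 to 15.7 M in C-IKKa (mean 13.9).

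The libraries differed most in hair follicle genes. The hair shaft and inner root sheath list holds keratins and keratin-associated proteins of growing hair. Its mean log2 value was between 10.2 and 12.3 in 6 libraries and between 2.51 and 5.35 in the other 12. The 6 high samples were WT 1 and 4, N-IKKa 8, 9 and 11, and C-IKKa 14. The list mean was 5.99 ± 4.46 (SD, n = 6) in WT, 7.25 ± 4.37 in N-IKKa and 5.01 ± 2.72 in C-IKKa. The first principal component held 57.4% of the variance and separated the same 6 libraries from the rest. As the libraries form separate clusters, its relation to the list mean was computed within each, a family of 4 permutation tests. The component was computed from all tested genes, the list included, and the clusters were set by the list mean. The 2 measures are therefore not independent of each other. Among the 12 low libraries Pearson's r was −0.767 (permutation p = 0.00129, adjusted 0.00516) and Spearman's rho was −0.741 (permutation p = 0.00796, adjusted 0.0159). Without the 2 libraries farthest from the median, r was −0.576. Among the 6 high libraries r was −0.814 (exact permutation p = 0.0486, adjusted 0.0486) and rho was −0.943 (exact permutation p = 0.0167, adjusted 0.0223), and r was −0.577 without the 2 farthest. The Y-linked gene Ddx3y exceeded 500 normalized counts in 2 WT, 2 N-IKKa and 4 C-IKKa libraries, which were read as male. All 6 high samples were among the 10 libraries read as female. Without them, WT keeps 2 female and 2 male libraries, N-IKKa 1 and 2, and C-IKKa 1 and 4, so fits without these samples change hair stage and sex together.

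**Figure D1:**
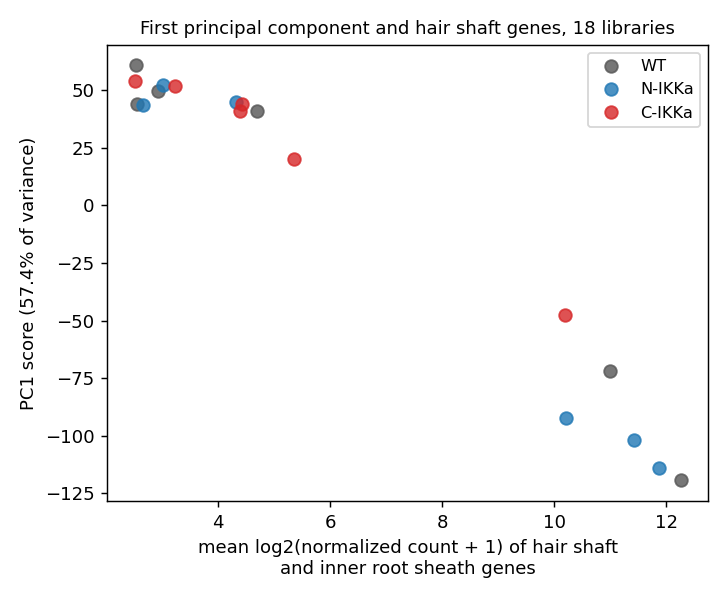
First principal component (57.4% of the variance, y axis) against the mean log2 value of the hair shaft and inner root sheath list (x axis), 1 point per library, coloured by group. The 6 libraries with a list mean of 10.2 or more stand apart from the other 12.

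Whether the transgenic groups carried more Chuk mRNA was read first. Chuk (ENSMUSG00000025199.17) averaged 1007 ± 147 normalized counts (SD, n = 6) in WT, 990 ± 93.3 in N-IKKa and 889 ± 26.3 in C-IKKa. The log2 fold change against WT was −0.02 in N-IKKa (SE 0.09, 95% limits −0.21 to 0.17, exact permutation p = 0.848). In C-IKKa it was −0.17 (SE 0.09, 95% limits −0.36 to 0.02, exact permutation p = 0.0563, adjusted 0.211). The C-IKKa value was −0.10 without WT 4 and −0.06 without the 6 high hair shaft samples. With all libraries, the limits allow at most a 1.13-fold rise in N-IKKa and a 1.01-fold rise in C-IKKa. N-IKKa against C-IKKa gave 0.15 (exact permutation p = 0.0346, adjusted 0.173). By limma, Chuk was not called in N-IKKa (adjusted p = 0.969) or C-IKKa (adjusted p = 0.948).

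The comparison of C-IKKa with WT asks what exogenous IKKα in the keratinocyte cytoplasm does to skin expression. Pglyrp2, Spib and Cxcl9 rose in C-IKKa skin. Pglyrp2 (ENSMUSG00000079563.11), an amidase that degrades bacterial peptidoglycan, rose from 12.3 ± 5.04 to 495 ± 271 normalized counts (SD, n = 6; log2 fold change 5.08, SE 0.38, limma adjusted p = 2.01e-06). Spib (ENSMUSG00000008193.14), an Ets-family transcription factor of B cells and plasmacytoid dendritic cells, rose from 8.22 ± 2.23 to 265 ± 151 (log2 fold change 4.67, SE 0.49, limma adjusted p = 7.66e-05). Cxcl9, a chemokine induced by interferon gamma that attracts T cells, rose from 36.6 ± 27.9 to 479 ± 181 (log2 fold change 3.80, SE 0.49, limma adjusted p = 0.00101). In all 3 genes, the 6 C-IKKa libraries lay above the 6 WT libraries.

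In total limma called 61 of 17667 genes higher and 0 lower in C-IKKa, and 53 of the 61 were at least 2-fold higher. At an unadjusted p below 0.05 there were 1012 genes, against 883 by chance. With edgeR 55 were called higher and 0 lower, and with DESeq2 134 higher and 14 lower. Groups did not overlap for 53 of the 61 and for 174 of all tested genes, where chance gives 0.216%, or 38.2 genes. Among the genes picked by size were also Ubd, a ubiquitin-like modifier (log2 fold change 4.66, SE 0.66), and Lingo2, a leucine-rich repeat membrane protein (4.24, SE 0.63). Others were Tafa2 (4.14, SE 0.78), Pld5 of the phospholipase D family (3.86, SE 0.51) and Cyp2j13, a cytochrome P450 (3.26, SE 0.49). Syt1, a calcium sensor of synaptic vesicles (3.40, SE 0.47), and Gabrg3, a GABA receptor subunit (3.21, SE 0.56), belonged to the same 10. Leaving out C-IKKa 13, 16, 17 or 18 lowered the 61 to 33, 33, 35 or 40 genes. The Tafa2 call was lost with edgeR (3.76) and without WT 2 or 3 or C-IKKa 13, 14, 16, 17 or 18 (3.79 to 4.19).

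**Figure D2:**
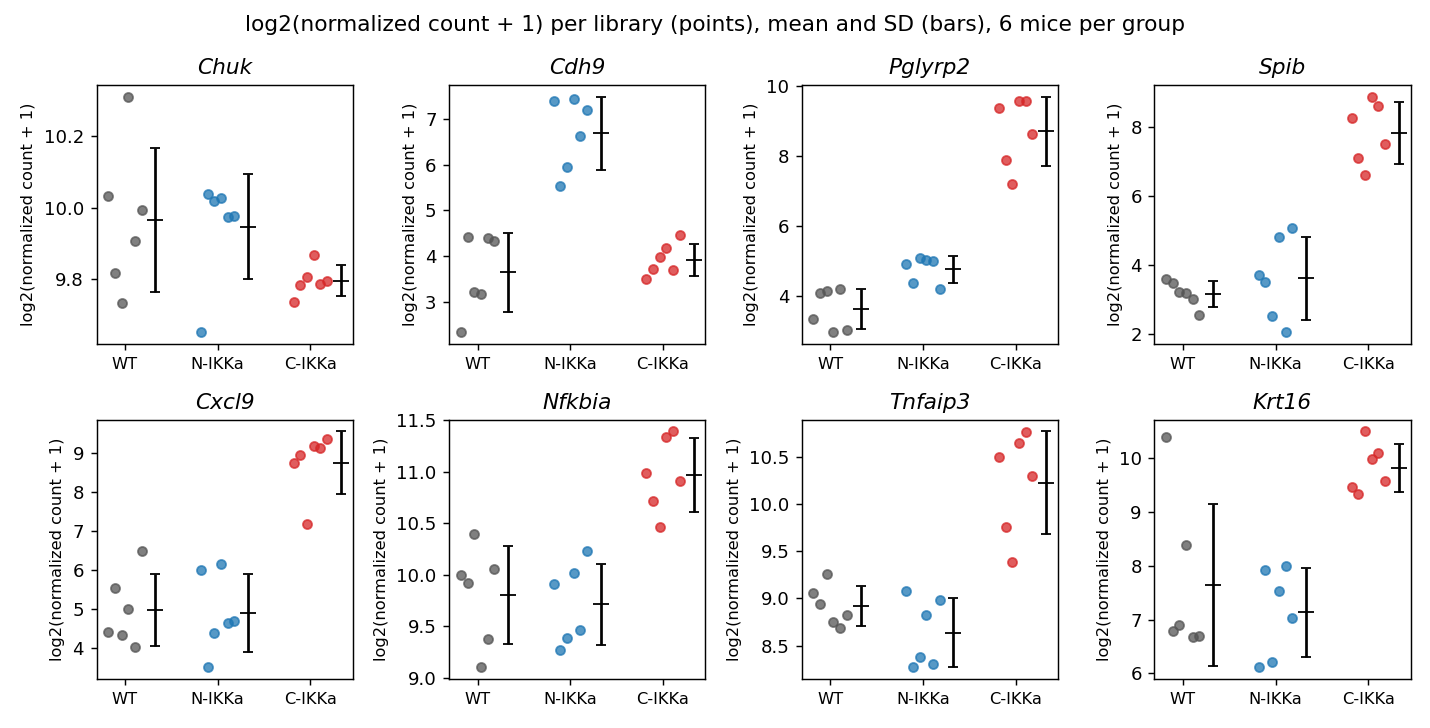
log2(normalized count + 1) of 8 genes in each library (points), with the mean and SD of 6 mice (bars), for WT, N-IKKa and C-IKKa. C-IKKa lies above WT and N-IKKa for Pglyrp2, Spib, Cxcl9, Nfkbia and Tnfaip3, N-IKKa lies above both for Cdh9, and Chuk means run from 889 to 1007 normalized counts.

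Among NF-kB target genes, 3 of 22 measured members rose in C-IKKa and 19 were not called; 10 rose adjusted over the list alone, and 21 of 22 had a positive log2 fold change (median 0.80). Icam1, an adhesion molecule for leukocytes, rose from 417 ± 74.4 to 1059 ± 281 normalized counts (SD, n = 6; log2 fold change 1.32, SE 0.22, limma adjusted p = 0.00908). Tnfaip3, a deubiquitinase that damps NF-kB signalling, rose from 488 ± 74.1 to 1262 ± 421 (1.30, SE 0.22, limma adjusted p = 0.00745). Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, rose from 932 ± 287 to 2051 ± 498 (1.16, SE 0.22, limma adjusted p = 0.0223). As a set the list was higher (camera adjusted p = 2.28e-17; adjusted p = 0.33 with an estimated correlation). Of 23 IKK and NF-kB pathway components, the same Tnfaip3 and Nfkbia rose, 2 in all, and 9 rose adjusted over the list alone (camera adjusted p = 6.13e-09; adjusted p = 0.357 with an estimated correlation). The Nfkbia call was lost without WT 5 or C-IKKa 13, 16, 17 or 18 (1.08 to 1.17).

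**Figure D3:**
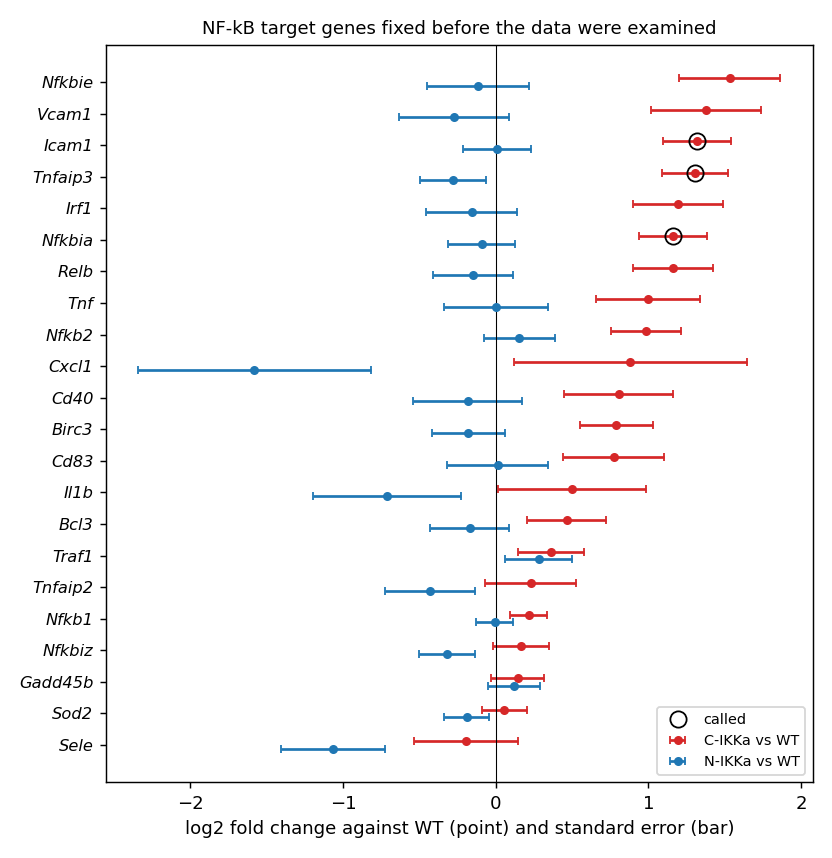
log2 fold change ± SE of the 22 measured NF-kB target genes in C-IKKa and N-IKKa, each against WT, with called genes circled. Icam1, Tnfaip3 and Nfkbia are circled for C-IKKa.

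Interferon and immune cell genes were examined next. Of 24 interferon-stimulated genes, 1 rose in C-IKKa, Cxcl9, and 1 did adjusted over the list alone; 22 of 24 were positive with a median of 0.34 (camera adjusted p = 3.89e-06; adjusted p = 0.666 with an estimated correlation). Of 14 Langerhans and dendritic cell markers, limma called 0, also adjusted over the list alone, 0 had an unadjusted p below 0.05, and edgeR and DESeq2 called 0. All 14 had positive values with a median of 0.55, among them Cd74 (0.83, SE 0.40) and H2-Ab1 (0.82, SE 0.41). The list was higher by camera (adjusted p = 0.00013; adjusted p = 0.666 with an estimated correlation). Of 16 T cell markers limma called 0, also adjusted over the list alone, with 1 at an unadjusted p below 0.05 and 0 by edgeR or DESeq2. The largest was Cd8a, the co-receptor of cytotoxic T cells (2.37, SE 0.76, limma adjusted p = 0.443), and the list median was 0.42 (camera adjusted p = 0.000974; adjusted p = 0.666 with an estimated correlation). The 5 B and plasma cell markers had a median of 1.34, including the immunoglobulin gene Igha (2.31, SE 0.91, limma adjusted p = 0.694; camera adjusted p = 0.0207, or adjusted p = 0.666 with an estimated correlation). Macrophage and monocyte markers had a median of 0.01 (camera adjusted p = 0.478). The dendritic cell mean of 0.58 was 0.38 without WT 4 and 0.26 without the 6 high hair shaft samples, and the list stayed called. The T cell list was not called without these samples (mean 0.33), nor was the B and plasma cell list (mean 1.02), which was also not called without WT 1 (0.88) or WT 2 (1.10).

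Camera put 8 lists higher and 2 lower in C-IKKa. The hair shaft list was negative in 29 of 30 genes (median −0.97, camera adjusted p = 0.035; adjusted p = 0.903 with an estimated correlation) and the mitochondrially encoded genes in 11 of 11 (median −0.14, camera adjusted p = 0.0242; adjusted p = 0.721 with an estimated correlation). The sebaceous gland list was positive in 16 of 20 (median 0.19, camera adjusted p = 0.0207; adjusted p = 0.666 with an estimated correlation). Limma called 0 members of these 3 lists, also adjusted over the list alone, with 1 mitochondrially encoded gene at an unadjusted p below 0.05, and edgeR and DESeq2 called 0. The hair shaft call was lost without WT 1 or 4 or C-IKKa 13, 15, 16 or 17 (mean −0.86 to 0.28), and the mean was −2.01 without C-IKKa 14. Without the 6 high hair shaft samples the hair shaft mean was 0.81 (camera adjusted p = 0.0105), the opposite direction. These samples were left out by the mean of this same list, so that value cannot decide about its direction. In that fit the mitochondrial and sebaceous gland means were −0.36 and 0.16. The sebaceous gland call was lost without WT 3 or 6 or C-IKKa 14 (mean 0.25 to 0.26). The call of mitochondrially encoded genes was lost without WT 3 or 5 or C-IKKa 16 or 18 (mean −0.12 to −0.07) or with quantile scaling (−0.12).

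Keratinocyte genes fixed in advance were not called in C-IKKa. Log2 fold changes were 0.15 (SE 0.13) for Krt5 and 0.02 (SE 0.13) for Krt14, keratins of the basal layer, and 0.25 (SE 0.40) for Krt1 and 0.29 (SE 0.37) for Krt10, keratins of differentiating layers. The cornified envelope genes Lor and Flg gave 0.40 (SE 0.41) and −0.52 (SE 0.25). Without WT 4, the lowest WT library in Krt1, Krt10 and Lor, these gave −0.08, −0.04 and 0.01, and without WT 1, the highest in Flg, Flg gave −0.28. With the 6 high hair shaft samples left out, Krt14 gave 0.20, Krt1 0.06, Krt10 −0.05, Lor 0.06 and Flg −0.26. Krt16, a keratin of stressed and wounded epidermis, averaged 353 ± 497 in WT and 945 ± 304 in C-IKKa (SD, n = 6; log2 fold change 2.19, SE 0.54, limma adjusted p = 0.138). It was called without WT 1 (2.74), which held 1351 normalized counts, with array weights (2.76), with the hair shaft covariate (2.32) or that covariate and sex (2.29), and without the 6 high hair shaft samples (3.16). Of 12 stress-induced keratinocyte genes limma called 0, with 2 called adjusted over the list alone, 2 at an unadjusted p below 0.05 and 0 by edgeR or DESeq2. Their median was −0.09 and their mean 0.25, on opposite sides of 0 (camera adjusted p = 0.311). Tnf, the inflammatory cytokine, gave 0.996 (SE 0.34, limma adjusted p = 0.519).

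Cdkn2a, a tumour suppressor gene that restrains the cell cycle and marks senescent cells, lay below the filter and was compared by exact permutation. It averaged 5.02 ± 3.01 normalized counts in WT, 3.58 ± 1.79 in N-IKKa and 21.7 ± 8.06 in C-IKKa (SD, n = 6). The log2 fold change was 2.02 in C-IKKa against WT and −2.31 in N-IKKa against C-IKKa (exact permutation p = 0.00216 for each, the smallest this design can give, adjusted 0.0162). All 6 C-IKKa libraries (9.79 to 33.1) lay above all 6 WT libraries (1.01 to 9.07). By limma without a filter, the adjusted p was 0.0613 in C-IKKa against WT and 0.0193 in N-IKKa against C-IKKa. Of the other genes below the filter, Krt6b (0.03), Lcn2 (−0.45) and Il6 (−0.59) had adjusted exact permutation p of 0.989, 0.65 and 0.321 in C-IKKa against WT. Of 13 measured senescence and secretory phenotype genes, which leave out Cdkn2a, limma called 0 in the same comparison. Among them 7 were positive and 6 negative (median 0.07, camera adjusted p = 0.578). The cell cycle list had a median of −0.03 (camera adjusted p = 0.983).

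The comparison of N-IKKa with WT asks the same of IKKα in the keratinocyte nucleus. Cdh9 (ENSMUSG00000025370.8), a cadherin that mediates adhesion between cells, rose in N-IKKa skin. It averaged 13.3 ± 7.27 normalized counts in WT, 115 ± 55.1 in N-IKKa and 14.5 ± 3.91 in C-IKKa (SD, n = 6; log2 fold change against WT 3.05, SE 0.40, limma adjusted p = 0.0086). The 6 N-IKKa libraries held 45.7 to 172.5 counts and the 6 WT libraries 4.0 to 20.2.

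Cdh9 was the 1 gene of 17667 called, and 0 were lower. At an unadjusted p below 0.05 there were 731 genes, against 883 by chance; edgeR called 1 higher and 0 lower, and DESeq2 called 1 higher and 1 lower. Groups did not overlap for 22 genes, where chance gives 0.216%, or 38.2 genes. The Cdh9 call was lost when the N-IKKa and WT libraries were fitted alone (log2 fold change 3.05).

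Of 532 measured list members, limma called 0 in N-IKKa against WT, with 21 at an unadjusted p below 0.05 and 0 by edgeR or DESeq2. Adjusted over the list alone, 1 of 22 cornified envelope genes fell, the protease gene Asprv1 that acts on filaggrin (−0.56, SE 0.16, limma adjusted p = 0.88 over all genes). Camera put 4 lists higher and 13 lower, and the smallest adjusted p was 0.666 with an estimated correlation. All 28 cell cycle genes were positive (median 0.57, camera adjusted p = 3.89e-06), among them the S phase regulator E2f1 (0.47, SE 0.19). All 12 Wnt target genes were positive (median 0.50, camera adjusted p = 3.89e-06), among them Apcdd1 (0.29, SE 0.10). The hair shaft list was positive in 29 of 30 genes (median 1.31, camera adjusted p = 0.0207), and the melanocyte markers in 8 of 8 (median 1.10, camera adjusted p = 0.0284). Cornified envelope genes had a median of −0.34 (19 of 22 negative, camera adjusted p = 0.000102). Skeletal muscle markers had a median of −0.57, with 18 of 18 negative (camera adjusted p = 2.24e-05), and macrophage and monocyte markers one of −0.42, with 15 of 15 negative (camera adjusted p = 0.000397). NF-kB target genes had a median of −0.16 (camera adjusted p = 0.0224). Without the 6 high hair shaft samples the cell cycle (mean 0.02), hair shaft (0.15) and melanocyte lists (0.20) were not called, and the NF-kB and macrophage means turned to 0.05 and 0.06. The hair shaft list defined these samples, so its own value there is not a test of it. The Wnt target (0.24), cornified envelope (−0.18) and skeletal muscle lists (−0.87) stayed called. Leaving out 1 library, the means ran from 0.27 to 0.73 for the cell cycle, −0.34 to −0.17 for the cornified envelope, −1.07 to −0.41 for skeletal muscle, −0.58 to −0.21 for macrophages and monocytes, and up to 2.51 for the hair shaft and 1.89 for melanocytes. The hair shaft (mean 0.33 to 0.996) and melanocyte calls (0.67 to 0.997) were lost without WT 2, 3, 5 or 6 or N-IKKa 8, 9 or 11, and the NF-kB call (−0.15 to −0.20) without WT 1 or 2 or N-IKKa 8, 9 or 11.

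Keratinocyte and inflammatory genes fixed in advance were not called in N-IKKa. Log2 fold changes were −0.12 (SE 0.13) for Krt5, −0.25 (SE 0.13) for Krt14, −0.53 (SE 0.40) for Krt1, −0.28 (SE 0.41) for Lor and 0.05 (SE 0.25) for Flg. The proliferation marker Mki67 gave 0.69 (SE 0.57), the cyclin gene Ccnd1 0.58 (SE 0.25) and the angiogenic factor Vegfa −0.45 (SE 0.20). The neutrophil chemoattractant Cxcl1 gave −1.58 (SE 0.76) and S100a9, an alarmin of neutrophils, −1.31 (SE 0.79). WT 1 held 1072.5 normalized counts of S100a9 and the other WT libraries 17.9 to 36.3; without WT 1 the log2 fold change was −0.40, and Krt14 and Flg gave −0.15 and 0.28. Without WT 4, the lowest in Krt1 and Lor, these gave −0.87 and −0.67. Mki67 lay between 2866.4 and 8959.3 normalized counts in the 6 high hair shaft samples and between 822 and 2114.6 in the other 12. With the 6 left out, Mki67 gave 0.05, Ccnd1 0.30, Vegfa −0.30, Krt5 0.13, Krt14 0.03, Krt1 −0.04, Lor −0.09, Flg 0.01 and S100a9 −0.50. With all libraries, limma adjusted p was 0.88 or more for each.

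The direct comparison of N-IKKa with C-IKKa sets the transgenic groups, which differ in the location of IKKα, against each other. They also differ in libraries read as male (2 in N-IKKa, 4 in C-IKKa) and in high hair shaft samples (3 and 1). An effect of location cannot be told apart from other differences between the groups. Cdh9 was higher in N-IKKa (log2 fold change 2.77, SE 0.40, limma adjusted p = 0.0016) and was the only gene called in that direction. Among the genes lower in N-IKKa, Ubd gave a log2 fold change of −4.53 (SE 0.66), Spib −4.22 (SE 0.49), Pglyrp2 −3.94 (SE 0.38) and Cxcl9 −3.87 (SE 0.49). Krt16 was lower as well, with 158 ± 81.1 normalized counts in N-IKKa and 945 ± 304 in C-IKKa (SD, n = 6; log2 fold change −2.69, SE 0.54, limma adjusted p = 0.0306).

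In total limma called 76 genes, 1 higher and 75 lower in N-IKKa, of which 65 were at least 2-fold apart and 65 had no overlap between groups (chance share 0.216%). At an unadjusted p below 0.05 there were 2059 genes, against 883 by chance. The genes picked by size also held Tafa2 (−4.21, SE 0.78), Pld5 (−3.91, SE 0.51), Syt1 (−3.74, SE 0.47), Gabrg3 (−3.61, SE 0.56), the adenylyl cyclase Adcy8 (−3.60, SE 0.55) and H2-K2, annotated as a transcribed pseudogene of the class I histocompatibility family (−3.80, SE 0.65). Leaving out N-IKKa 11 or C-IKKa 13, 16 or 17 lowered the 76 to 50, 49, 40 or 39 genes. Without C-IKKa 16 or 17 (−4.17 and −4.16) or with edgeR (−3.85), Tafa2 was not called.

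All 22 NF-kB target genes had lower values in N-IKKa than in C-IKKa (median −0.98): 5 fell, 17 were not called, and 18 fell adjusted over the list alone. The 5 were Nfkbia and, in order of size, Nfkbie, an inhibitor of NF-kB (−1.65, SE 0.33), Tnfaip3 (−1.58, SE 0.22), Relb, a subunit of the noncanonical NF-kB pathway (−1.31, SE 0.26), and Icam1 (−1.31, SE 0.22). The list was lower by camera (adjusted p = 8.74e-17; adjusted p = 0.33 with an estimated correlation). Of 23 pathway components 5 fell, 9 adjusted over the list alone (camera adjusted p = 1.86e-07; adjusted p = 0.465 with an estimated correlation). Of 24 interferon-stimulated genes 1 fell, Cxcl9, and 4 fell adjusted over the list alone; all 24 were negative (median −0.72, camera adjusted p = 2.74e-09; adjusted p = 0.666 with an estimated correlation), and the mean of −0.84 was −0.48 without the 6 high hair shaft samples. The calls of Krt16 (−2.49 to −2.77), Nfkbie (−1.46 to −1.65) and Relb (−1.19 to −1.35) were each lost without C-IKKa 13, 16, 17 or 18, or without N-IKKa 9. Krt16 was also not called without N-IKKa 7 or 12, without C-IKKa 15 or with edgeR (−2.57), and Nfkbie and Relb were not without N-IKKa 8 or 11, or with a sex covariate for Nfkbie (−1.48) and the pair of groups alone for Relb (−1.31). Without the 6 high hair shaft samples, Icam1 (−0.92), Nfkbia (−0.96), Relb (−0.998) and Ubd (−4.31) were not called.

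Cell type marker lists were compared between the same groups. Langerhans and dendritic cell markers had a median of −0.87 in N-IKKa against C-IKKa (14 of 14 negative, camera adjusted p = 1.25e-05), T cell markers −0.54 (16 of 16 negative, camera adjusted p = 0.000387) and macrophage and monocyte markers −0.47 (15 of 15 negative, camera adjusted p = 0.00093). The hair shaft list had a median of 2.34 (30 of 30 positive, camera adjusted p = 0.000434) and the sebaceous gland list −0.59 (18 of 20 negative, camera adjusted p = 1.82e-05). With an estimated correlation the first 3 had an adjusted p = 0.666, the hair shaft list an adjusted p = 0.788 and the sebaceous gland list an adjusted p = 0.551. Limma called 0 members of these 5 lists; at an unadjusted p below 0.05 there were 5, 3, 1, 0 and 9, edgeR called 0, and DESeq2 called 0 except for 1 macrophage and monocyte marker. Adjusted over the list alone, 1 T cell marker and 1 macrophage and monocyte marker fell. Once the 6 high hair shaft samples were left out, the macrophage and hair shaft means turned to 0.01 and −0.65; the T cell mean (−0.07) and the dendritic cell mean (−0.06) were not called, and the sebaceous gland mean of −0.58 was −0.22 and stayed called. The high samples were defined by the hair shaft list, so its own mean without them is not a test of it. Leaving out 1 library, the macrophage mean ran from −0.67 to −0.30 and the hair shaft mean from 1.31 to 3.27.

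The title of the series speaks of opposite phenotypes, so the changes of the transgenic groups were set side by side. Of the 61 genes higher in C-IKKa than in WT and the 75 lower in N-IKKa than in C-IKKa, 48 were shared, against 0.259 for independent lists. The lists share the C-IKKa libraries: with these split 3 and 3 between the comparisons, the overlap over 20 splits was 5 to 12 with a median of 5, against 0.0142 for independent lists. The 61 genes had a median log2 fold change of 2.07 in C-IKKa against WT and of 0.02 in N-IKKa against WT, where 27 of the 61 were negative. Across all 17667 genes, which are not independent replicates, the correlation of the fold changes against WT was −0.01 (jackknife SE 0.48). Leaving out 1 library it ran from −0.14 without N-IKKa 12 to 0.28 without WT 4, and with the hair shaft covariate it was 0.35. Unchanged groups of 6 were simulated by drawing library profiles with replacement from all 18 libraries, after group means were removed. A drawn group served as the shared reference. These gave a median correlation of 0.55 (95% range −0.45 to 0.93), and their covariance averaged 0.0746 (−0.0645 to 0.340), with −8e-04 observed. With the WT libraries split 3 and 3 the median was −0.28 (−0.71 to −0.05), and without the 6 high hair shaft samples the correlation was 0.50.

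**Figure D4:**
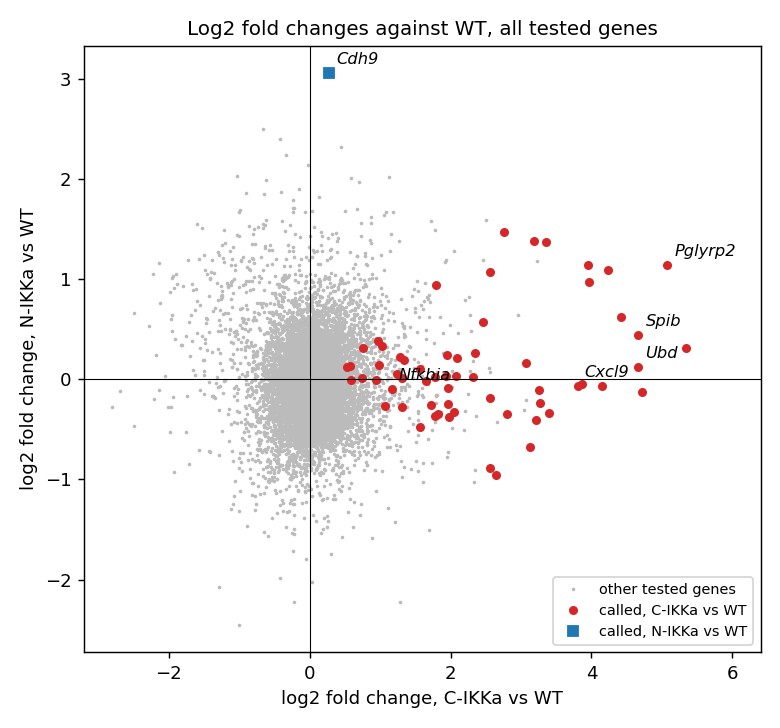
log2 fold change of each of 17667 genes in C-IKKa against WT (x axis) and in N-IKKa against WT (y axis), with called genes coloured. The 61 genes called in C-IKKa spread to the right with a median of 2.07 on the x axis and 0.02 on the y axis, and Cdh9 stands alone at 3.05 on the y axis.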

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

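The tests with the hair shaft covariate, the thinning of reads and the interval of Chuk were chosen only after the result was seen.

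The first pattern is the 61 genes higher in C-IKKa than in WT. With the hair shaft list mean as a covariate 61 of the 61 stayed called (median log2 fold change 2.05 against 2.07 without it), which argues against hair follicle stage as the whole source. With the mean of 63 immune cell markers as a covariate 59 stayed called (median 2.12), which argues against a rise shared by these markers as the whole source. The mean pools markers of several immune cell types, so it cannot decide about a rise of only some of them. With all libraries thinned to the smallest or with a sex covariate 57 stayed called, which argues against fewer WT reads or sex. Of 100 splits drawn from the 462 splits of the 12 libraries, 1 called as many genes, the real one, and the highest other called 2. This argues against chance for the count of 61, though the splits not drawn were not examined. An effect of cytoplasmic IKKα is a candidate explanation that may be followed up. Litter, founder line, a preparation or sequencing batch, a partial share of immune cells and a rise of only some immune cell types stay open and were not tested. The labels give no batch, and replicate numbers run in group order. Reads reached at most 12.629 M in WT and were at least 12.645 M in C-IKKa. A batch that followed the groups could not be told apart from genotype.

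The second pattern is Cdh9, higher in N-IKKa alone of the 3 groups. Of the 10 nearest tested genes, 1 had an unadjusted p below 0.05, Drosha (log2 fold change 0.32, limma adjusted p = 0.88). This count cannot decide about a shared local effect, because some neighbours varied widely, such as Cdh6 (0.94, SE 1.24) and Cdh18 (0.17, SE 0.99). Golph3 (−0.03, SE 0.07), Pdzd2 (0.04, SE 0.08) and 6030458C11Rik (0.04, SE 0.09) were measured closely and did not share a rise of the size of Cdh9. The neighbours were taken by gene order without a limit on distance. How far they lie from Cdh9 was not measured, so these flat values do not decide about a local effect either. With the hair shaft covariate the Cdh9 log2 fold change was 3.21 against 3.05 and stayed called, which argues against hair follicle stage. Of 100 splits of the WT and N-IKKa libraries, 7 called at least 1 gene and the highest other called 7371, so chance could not be excluded for the count of 1. In the splits that called 7371 and 7320 genes, the hair shaft list mean differed by 6.54 and 7.12 between the groups. In the real split it differed by 1.26. This test counts called genes, some of them set apart by hair shaft values, and does not decide about Cdh9 itself. An effect of nuclear IKKα on Cdh9 may account for the value, and a local effect on Cdh9 alone was not tested.

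The third pattern is that Chuk was not higher in either transgenic group. The larger of the upper 95% limits of its log2 fold change was 0.17, below the 1 that transgene mRNA as abundant as endogenous Chuk mRNA and counted as Chuk would need. When genes were called without a given C-IKKa library, 6 of 6 C-IKKa libraries lay above all WT and N-IKKa libraries on those genes, which argues against a library wrongly labelled C-IKKa. A transgene transcript that is rarer than Chuk mRNA in whole skin, or that is not counted under Chuk, may be present and was not tested. No biological explanation was tested.

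The count of 76 genes between N-IKKa and C-IKKa was reached in 1 of 100 splits, the real one, and the highest other called 0. This argues against chance for the count of 76, though the splits not drawn were not examined. For the number of gene lists called, chance could not be excluded. In N-IKKa against WT, 27 of 100 splits called as many as the 17 real lists (highest other 22). In C-IKKa against WT, 78 did (10 real, highest other 19), and in N-IKKa against C-IKKa, 7 did (20 real, highest other 22). For single lists, the number of the 100 splits that were as strong is given with the real one included. In C-IKKa against WT it was 2 for NF-kB target genes, 1 for IKK and NF-kB pathway components, 1 for sebaceous gland, 8 for circadian output, 12 for B and plasma cell, 13 for dendritic cell, 14 for T cell, 14 for interferon-stimulated, 44 for mitochondrially encoded and 75 for hair shaft genes. In N-IKKa against C-IKKa it was 1 for NF-kB target genes, 1 for pathway components, 7 for sebaceous gland, 9 for interferon-stimulated, 10 for dendritic cell, 18 for T cell, 26 for macrophage and 56 for hair shaft genes. In N-IKKa against WT it was 2 for Wnt target, 4 for cornified envelope, 25 for skeletal muscle, 26 for macrophage, 31 for cell cycle, 44 for melanocyte, 44 for NF-kB target and 81 for hair shaft genes.

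In 16 of 126 sets of 6 values, 1 library stood apart from the other 5 by more than Dixon's 95% critical share of the range. For normally distributed values, chance gives about 1 in 20. In WT 4, Krt1 was 3070 normalized counts (others 9530 to 15000), Krt10 was 10500 (33200 to 49200) and Lor was 871 (2980 to 5800), while Ivl was highest there at 4610.9 (1571.8 to 3066.3). In WT 1, Flg was 5670 (others 1820 to 2270), S100a9 was 1070 (17.9 to 36.3), Il1b was 154 (29.2 to 47.9) and Cyp2j13 was 1.01 (4.57 to 7.06). N-IKKa 7 had the lowest Chuk value, 804 (others 1000 to 1050), and the highest Krt6b value, 6.46 (0.88 to 2.05). The Cyp2j13 and Krt6b values rest on few reads, as 1 read was worth 1.01 normalized counts in WT 1 and 0.923 in N-IKKa 7. N-IKKa 9 had the lowest Krt14 value, 7770 (others 10100 to 11200). C-IKKa 14 had the highest Ccnd1 value, 1330 (767 to 933), Tgfa value, 1290 (856 to 955), and hair shaft list mean, 10.2 (2.51 to 5.35). C-IKKa 15 was lowest in Lingo2 at 174 (441 to 749), Pld5 at 160 (406 to 628) and Cxcl9 at 145 (429 to 656).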

How the results depend on the processing

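The hair shaft settings and the thinning of reads were chosen after the data were seen. No paired analysis was possible because replicate numbers run from 1 to 18 over the groups and none is shared. Calls in N-IKKa against WT, C-IKKa against WT and N-IKKa against C-IKKa (1, 61 and 76 genes) stayed within 1.5 times under pseudocounts, TMM, median-of-ratios and quantile scaling, edgeR, robust moderation, the sex covariate, the 2-fold limit and thinned reads. Both Chuk fold changes against WT stayed uncalled in all settings, though that of N-IKKa ran from −0.06 to 0.06. That of C-IKKa moved to −0.10 without WT 4 and to −0.06 without the 6 high hair shaft samples. Without a filter 2 genes were called in N-IKKa against WT; the cause was not tested. A filter of 50, which tests fewer genes, gave 0, 38 and 47. DESeq2 gave 2, 148 and 188, and array weights gave 176 and 163 in the comparisons with C-IKKa; the cause was not tested. With N-IKKa and WT fitted alone, 0 genes were called, with fewer samples to estimate the spread. The hair shaft covariate gave 164 and 157 in the comparisons with C-IKKa, and with sex added 152 and 178; the cause was not tested. Without the 6 high hair shaft samples 2 and 163 genes were called against WT, and the correlation of fold changes was 0.50; the cause was not tested. Leaving out 1 library gave 1 to 2, 33 to 73 and 39 to 103 genes. Of 47 gene list calls, 0 were kept with an estimated correlation, with or without the hair shaft covariate, which widens the spread expected of a list. Without the 6 high hair shaft samples, all read as female, 17 called lists changed direction relative to other genes, and the mean log2 fold change of 15 of them changed sign; the cause was not tested. In N-IKKa against WT these were inflammatory cytokines (0.040), NF-kB targets (0.048), macrophage (0.061), matrix enzymes (0.15), sebaceous gland (−0.058, sign kept) and ceramide synthesis (0.029), and in C-IKKa against WT the hair shaft (0.81, called). In N-IKKa against C-IKKa they were T cell (−0.0725, sign kept), Wnt targets (−0.13), macrophage (0.0061), mast cell (0.053), hair shaft (−0.65), adipocyte (0.071), endothelial (0.19, called), melanocyte (−0.42), cell cycle (−0.28, called) and circadian output (0.0057). The hair shaft list set the cut that left these samples out, so its own values in this fit cannot decide about its direction. Leaving out 1 library, the hair shaft mean in C-IKKa against WT ran from −2.01 to 0.28, the latter without WT 4; the cause was not tested. Depth sets a limit of 2.45 to 3.61 normalized counts for a value of 0.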

Other observations

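The genes in this part and the fits with the hair shaft covariate were chosen after the values were seen. No list of genes for class I antigen presentation was fixed in advance or tested as a set. The 8 single genes that follow were called in C-IKKa against WT once the hair shaft list mean was a covariate, while the class I gene H2-D1 was not. The peptide transporter genes Tap2 and Tap1 had log2 fold changes of 0.80 (SE 0.11, limma adjusted p = 0.000664) and 0.67 (SE 0.11, limma adjusted p = 0.00285), n = 6 mice per group. Tapbp, their partner, had 0.67 (SE 0.10), and the immunoproteasome genes Psmb9 and Psmb8 had 0.95 (SE 0.15) and 1.05 (SE 0.19). The class I genes H2-K1 and H2-Q4 had 0.64 (SE 0.12) and 0.82 (SE 0.15), and Irf1, a transcription factor that induces them, had 1.07 (SE 0.15). Without the covariate limma called none of these 8 (adjusted p from 0.138 for Irf1 to 0.616 for Tap1), and without the 6 high hair shaft samples it called each of them (adjusted p from 0.00338 for Irf1 to 0.0489 for Psmb8). Other genes looked at with these 8 were less uniform. Nlrc5 was called with the covariate (limma adjusted p = 0.0479) but not without the 6 samples (0.267). Psme2 was called already without the covariate (limma adjusted p = 0.0223). With the same covariate, Relb (1.06, SE 0.14), Nfkbie (1.41, SE 0.20), Nfkb2 (0.94, SE 0.21) and Birc3 (0.70, SE 0.14) were also called, and 8 of 22 NF-kB target genes rose in C-IKKa. Without the covariate these 4 had a limma adjusted p of 0.0815, 0.0637, 0.104 and 0.358. Without the 6 high hair shaft samples Relb (0.02) and Nfkbie (0.00338) were called, and Nfkb2 (0.114) and Birc3 (0.0541) were not.

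The 61 genes higher in C-IKKa also held the synaptic vesicle gene Syn2 (35.1 ± 16.3 normalized counts in WT and 209 ± 76.7 in C-IKKa, SD, n = 6; log2 fold change 2.56) and the potassium channel gene Kcnq3 (56.2 ± 26.4 and 297 ± 137; 2.35). No list of neuronal genes was tested; the list of Schwann cell and nerve markers had a median log2 fold change of 0.00 over 9 measured members in the same comparison (camera adjusted p = 0.94). Others among the 61 were Nod2, a sensor of bacterial peptidoglycan (233 ± 57.2 and 907 ± 200.8; 1.97), the chemokine gene Ccl1 (3.95), the lipoxygenase gene Alox12e (1.78), Chil1 (1.78), the sphingosine phosphate receptor gene S1pr3 (2.46) and Trp73, a relative of p53 (0.76).

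Circadian output genes were positive in 8 of 8 measured members in C-IKKa against WT (median log2 fold change 0.51, camera adjusted p = 0.000174; adjusted p = 0.666 with an estimated correlation), with Dbp at 1.34 (SE 0.57, limma adjusted p = 0.77). Limma called 0 of the 8, with 2 at an unadjusted p below 0.05, and edgeR and DESeq2 called 0. The list mean of 0.63 was 0.31 without the 6 high hair shaft samples. The hour at which skin was taken is not given in the sources used here. Xist was listed at 0 in all 18 libraries, 10 of them read as female, and Tsix reached 38.8 normalized counts. Of the exon length of Xist, 11.5% is overlapped on the opposite strand. Such a share does not by itself account for a 0, as Ccnd1, overlapped over 23.4%, held 767 to 1330 normalized counts in C-IKKa. The strand setting of the counting step is not given in the sources used here. The cause of the 0 was not tested, so it cannot be read as absence of the Xist transcript. In the libraries read as female, the sum of Y-linked transcripts was 0.24% to 2.69% of the male mean in WT, with 2.69% in WT 2, and at most 0.33% in the transgenic groups.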
